A study of Mus musculus with 2 samples.

How the data were processed

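RNA of mouse liver was measured on 2 arrays with biotin-labelled cDNA. Per the labels' protocols, C57BL/6J mice of 6 to 10 weeks had a catheter placed in the jugular vein on day 1, received saline through it from day 2, and from day 3 either continued on saline with access to food or received parenteral nutrition (PN, nutrients infused into a vein) with the food removed. Liver was collected on day 11. Per the series' design text, RNA of 3 mice of each group was pooled, and each pool was hybridised to 1 array. The groups were taken from the mouse group given in the labels.

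The deposited table holds log2 values: 1 value per probe set and array. Per the submitters' processing notes the authors used RMA (robust multi-array average: background correction, normalization between arrays and summary of the probes of a probe set) in Affymetrix Expression Console 1.4.0.38. The genome build, the probe annotation and the set of arrays normalized together are not given in the sources used here. Per the series' design text the deposited rows were kept by a 1.5-fold cutoff. On the table itself, the smallest absolute difference between the arrays was 0.585 on the log2 scale, against 0.585 for a fold of 1.5, so every row differed by at least that much. A gene that is not in the table therefore has no value here: it differed by less, carries no name here or was not measured. Shares of all measured genes, enrichment against unchanged genes and statements that a gene did not differ cannot be had from such a table.

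Of the 5082 rows, 1779 carried 1 gene symbol in the platform annotation, 161 several and 3142 none. Of the rows with 1 symbol, 1766 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and 1457 of the rows were protein coding. Older symbols in the gene lists were updated through the synonyms of that table. Rows with several symbols named no gene. Rows with 1 symbol were averaged per gene, which gave 1750 named genes. Another row's pair of values was repeated by 123 rows, as rows of near-identical gene copies do. Of 22 genes with more than 1 row, 18 had all rows in the same direction. Probe sets of close paralogs can share target sequence, so values of such genes are uncertain.

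The difference of a gene is the PN value minus the saline value on the log2 scale, with no pseudocount. A fold is 2 to the power of that difference. The median higher level of the 133 chemosensory receptor genes in the table, 3.26, was taken as a background level after seeing the data. Where 1 of a gene's 2 levels lay under it, that level was raised to it and the fold is given as at least that size. Receptor genes also lie above this median, so such a fold is a bound only relative to this chosen level. With 1 array per group there is no replicate check: no p-value, standard error or false discovery rate was computed, pooling removes the spread between mice, and the 2 arrays limit the precision. Every comparison describes these 2 pools.

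A total of 32 gene lists, 23 of pathways or responses and 9 of cell type markers, were written before the data were examined, as were the rule for named genes and the first set of alternatives given below. For each list the members in the table, their direction and their median difference were recorded. For lists with at least 3 members in the table, the median was placed among the medians of 10000 random lists of the same size. The random lists were drawn from the named genes, matched on mean level in 10 bins. Since the cutoff leaves no differences near 0, the number of higher members was placed among the same random lists as well, a choice made after seeing the data. Both percentiles describe the directions within a table of genes selected for differing and are not tests of the conditions. For all rows and for lists with at least 5 members, exact Clopper-Pearson 95% intervals of the share of higher members were used to judge the alternatives and, after seeing the data, to set the markers of other cell types beside those of macrophages. These intervals treat the members as independent draws and do not measure uncertainty about the pools.

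The scripts were tested on simulated data made from the 1750 named genes, with 100 simulated lists of 12 members each. The percentile of the count lay above 97.5 for 100 of 100 lists with all members higher. The percentile of the median did so for 53 of these lists, and for 100 of 100 when 0.50 was added to the differences. With random directions, 5 of 100 lists fell outside 2.5 to 97.5 by the median and 4 by the count. The simulated sizes were shuffled over genes and the directions drawn independently. The simulation thus checks the calculation, not how often real lists of related genes would fall outside.

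Named genes are the 12 genes with the highest and the 12 with the lowest difference among genes whose higher value was at or above the median of that value over named genes, 5.18. Predicted and RIKEN genes, small RNA genes, chemosensory receptor genes and immunoglobulin or T cell receptor segments were left out. In addition, the up to 4 members with the largest absolute difference were named for each list. The alternatives were cutoffs of 2-fold and 3-fold, bright rows or genes only, centring each array on its median, counting genes in place of rows, the brightest row per gene, rows with several symbols counted for each gene, and random lists not matched on level. Alternatives added after seeing the data were a filter at the 95th percentile of the absolute difference of chemosensory receptor genes, lists without members of the sex-biased lists, rows with or without a gene name, and named genes with levels raised to the background level. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.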

Results

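Liver RNA from mice on parenteral nutrition (PN) was compared with liver RNA from saline-infused mice that kept access to food. The aim was to describe how the liver transcriptome differed after 8 days of PN or of continued saline. Each group was represented by 1 array of RNA pooled from 3 C57BL/6J mice, a common inbred laboratory strain, so no difference below has a replicate check and no test between the groups was possible. The infusion and the removal of food differed together between the pools. Values are RMA levels on the log2 scale, which ran from 1.32 to 12.5 in the saline pool and from 1.38 to 11.8 in the PN pool, with medians of 4.37 and 4.36. The deposited table had been restricted by the authors to rows that differed by at least 1.5-fold, so a gene without a value here is not thereby unchanged.

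Of the 5082 rows, 2405 were higher and 2677 lower in the PN pool, and 1373 differed by at least 2-fold. Among the 1750 named genes, 878 were higher and 872 lower. Among named genes of at least median level, Sult1e1, an estrogen sulfotransferase, had the highest difference. Its saline level of 2.91 lay under 3.26, the median level of chemosensory receptor genes that serves as a background level here, so its PN level of 7.02 was at least 13.5-fold higher. Cyp2b9, a cytochrome P450, was 9.40-fold higher. Slc22a27, an organic anion transporter family member, was 7.24-fold higher, from a saline level of 3.31 that lay close to background. Lepr, the leptin receptor, was 7.05-fold higher. Abcd2, a peroxisomal fatty acyl transporter, was 5.97-fold higher and Cyp17a1, a steroid hydroxylase, 5.28-fold higher. The nuclear receptor gene Nr4a1 was 5.16-fold higher, the scavenger receptor gene Marco 5.15-fold, the transcription factor gene Egr1 5.10-fold, the clock-controlled gene Noct 5.02-fold and the antiproliferative gene Btg2 4.64-fold. Trim43c was 6.51-fold higher, but it belongs to a group of close paralogs, so which copy was measured is uncertain.

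At the other end, Cyp4a12a, a fatty acid hydroxylase of male mouse liver, was 9.17-fold lower in the PN pool, from 7.50 to 4.30. Its close paralog Cyp4a12b was 4.87-fold lower. The P450 genes Cyp2b10 and Cyp2a5, known as targets of the xenobiotic receptor CAR, were 6.72-fold and 3.81-fold lower. Orm3 and Orm2, paralogs that encode orosomucoid plasma proteins, were 6.61-fold and 6.07-fold lower. Clec2h, a C-type lectin gene, was 6.12-fold lower, and Selenbp2 4.49-fold lower. Cyp8b1, the sterol 12-hydroxylase that directs bile acid synthesis to cholic acid, was 3.56-fold lower. Ppp1r3c, a glycogen-targeting phosphatase subunit, was 3.55-fold lower, Aoc1 3.47-fold and Akr1c6 3.44-fold. Both rankings leave out small RNA genes and the other classes given with the processing. Of the 12 highest genes 5 were members of the list of female-biased liver genes and none of the male-biased list. Of the 12 lowest genes 3 were members of the male-biased list and none of the female-biased list.

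**Figure D1:**
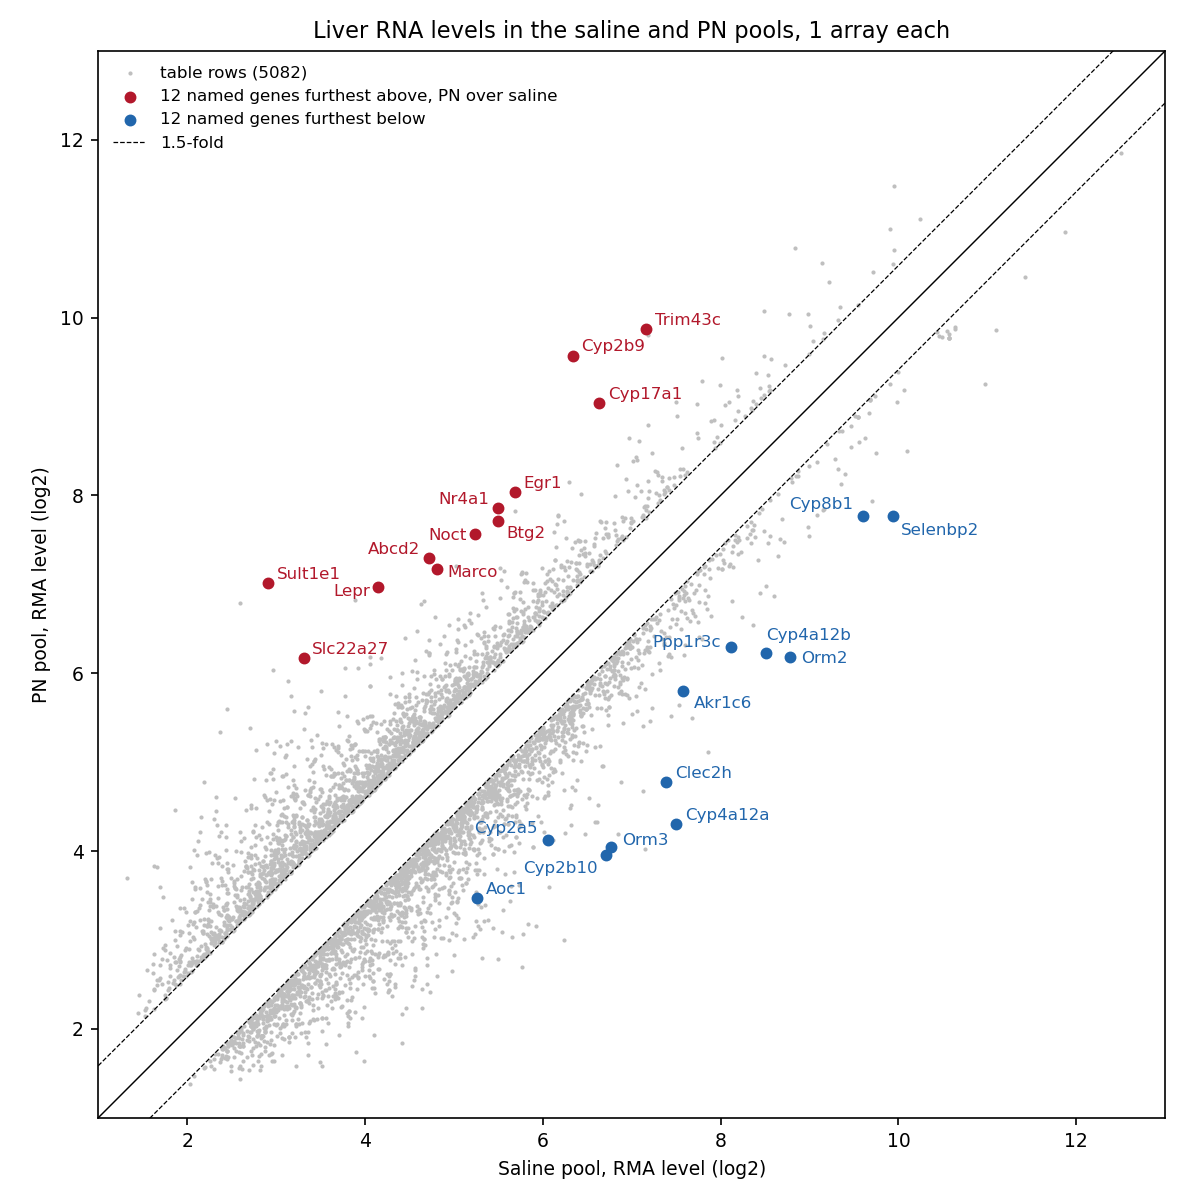
RMA level (log2) of every deposited row in the saline pool (x axis) and the PN pool (y axis), 1 array each. The dashed lines mark 1.5-fold, inside which no row lies. Coloured points are the 12 ranked genes furthest above the diagonal, up to Sult1e1 at 7.02 in the PN pool and 2.91 in the saline pool, and the 12 furthest below, down to Cyp4a12a at 9.17-fold lower. Ranked genes are named genes of at least median level, without small RNA genes and the other left-out classes.

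Genes known to differ between male and female mouse liver went in opposite directions in the male-biased and female-biased lists. All 18 male-biased genes in the table were lower in the PN pool, by a median of -1.19 on the log2 scale (2.28-fold lower). Besides Cyp4a12a, Cyp4a12b and Selenbp2, these included Elovl3, a fatty acid elongase, which was 3.01-fold lower. Of the 16 female-biased genes in the table, 15 were higher, and the median of all 16 was 1.15 (2.21-fold higher), or 0.97 (1.96-fold) with levels under the background level raised to it. Sult1e1, Cyp2b9, Slc22a27 and Abcd2 had the largest differences. The exception, Sult2a5, was at least 1.92-fold lower, at levels of 4.20 and 3.23. It is singled out here after its value was seen. The male-biased median lay at percentile 0 of the random lists, and the female-biased median at percentile 100. The lists held 17 further male-biased and 20 further female-biased genes without a named value in the table. The labels used here give no sex for the mice.

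**Figure D2:**
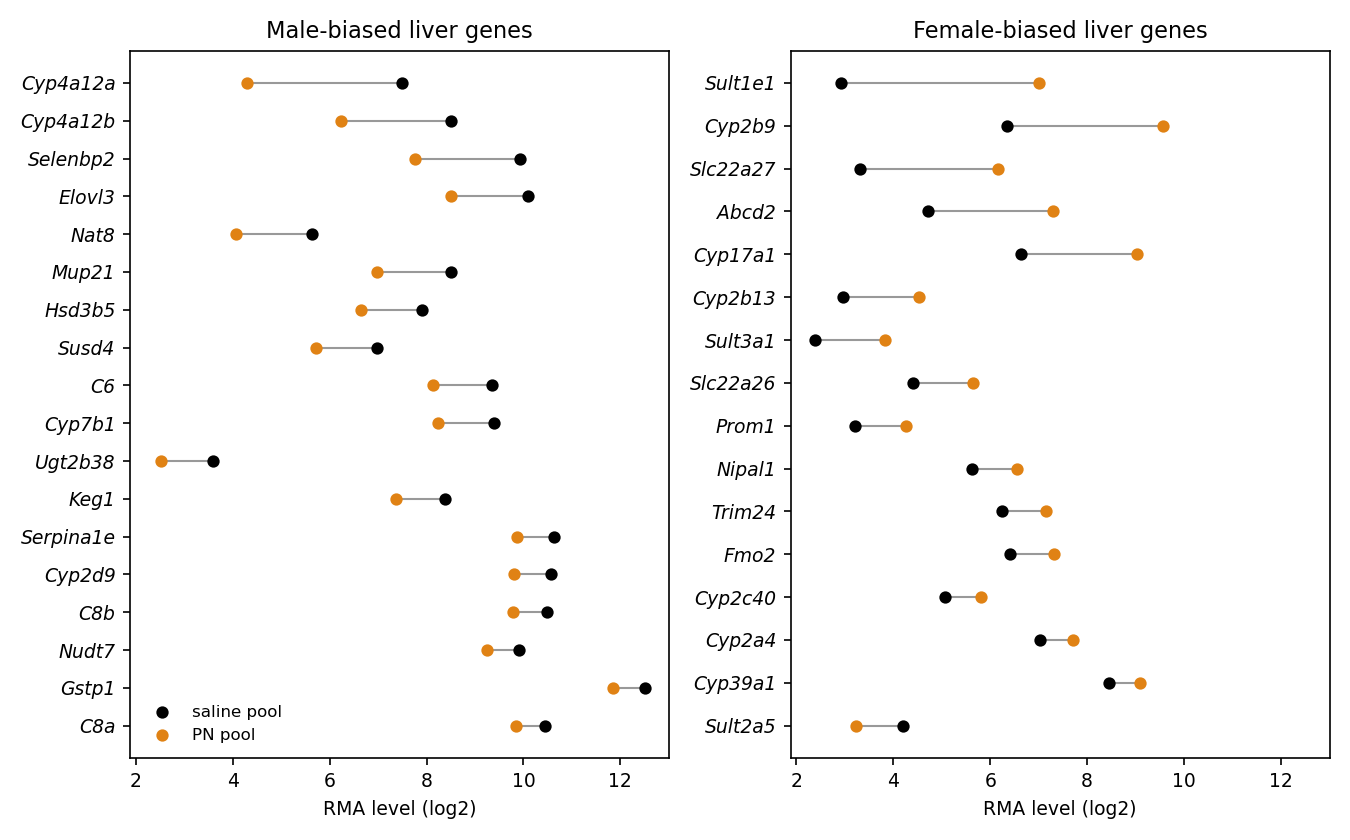
RMA level (log2, x axis) of each member of the male-biased (left, 18 genes) and female-biased (right, 16 genes) lists found in the deposited table, with black points for the saline pool and orange points for the PN pool, 1 array each. All 18 male-biased genes lie lower in the PN pool, and all female-biased genes except Sult2a5 lie higher.

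Genes of gluconeogenesis and the fasting response were higher in the PN pool. All 8 members in the table, of 16 listed, were higher, with a median of 1.21 (2.32-fold). Beside Lepr, Igfbp1, an insulin-repressed growth factor binding protein, was 2.88-fold higher, Sik1, a kinase induced by cyclic AMP, 2.78-fold and the coactivator gene Ppargc1a 2.38-fold. The median lay at percentile 99.9 and the count of higher members at percentile 99.7 of the random lists. Among genes past a 2-fold cutoff the median lay at percentile 91.7. Immediate early genes, which are transcribed within minutes of a stimulus, were higher in all 11 members with a value, of 21 listed, with a median of 0.96 (1.95-fold). Egr1 and Btg2 led this list, followed by Gadd45g at 3.21-fold and Jun at 2.75-fold. This median lay at percentile 99.8.

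Few genes of lipid synthesis had a named value. Of the 26 genes of cholesterol synthesis and uptake 21 had none, and the 5 with a value were higher, with a median of 0.77 (1.71-fold). Sqle, squalene epoxidase, was 2.01-fold higher, Mvd 1.78-fold, Fdps 1.71-fold and Hsd17b7 1.68-fold. The count lay at percentile 98.7 of the random lists and the median at percentile 86.5. Of the 28 genes of fatty acid and triglyceride synthesis 23 had no named value, and 4 of the 5 others were higher. Fasn, fatty acid synthase, was 1.95-fold higher, Fads2 1.82-fold and Elovl6 1.66-fold, whereas Elovl3, also a member of the male-biased list, was lower. The count lay at percentile 88.5 and the median of 0.73 at percentile 82.6, and past a 2-fold cutoff Elovl3 alone was left, which turns the direction. Of the 35 genes of the fatty acid oxidation and PPARA list, 3 had a named value. Fgf21, a fasting-induced hormone gene, was 1.85-fold higher, Crat 1.59-fold and Acot4 1.58-fold. The median of these 3 lay at percentile 76.6. A row shared by Cyp4a10 and Cyp4a32, both also on this list, was not counted here and was 2.74-fold lower. That row is named after its value was seen. Of 26 lipid droplet and lipoprotein genes 4 had a value, and 3 of these were higher. Apoa4 was 2.77-fold higher, the phospholipid transfer protein gene Pltp 1.97-fold and the lipoprotein lipase gene Lpl 1.76-fold, while Plin5, a lipid droplet coat protein gene, was 1.74-fold lower. This median lay at percentile 92.3.

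The 4 bile acid synthesis genes in the table, of 16 listed, split evenly. Cyp7a1, the rate-limiting enzyme of the classical pathway, was 2.41-fold higher in the PN pool, from 8.77 to 10.0, and Cyp39a1 was 1.56-fold higher. Cyp8b1 was lower, as given above, and Cyp7b1, the oxysterol hydroxylase of the alternative pathway, was 2.22-fold lower. Cyp7b1 and Cyp39a1 are also members of the male-biased and the female-biased list, respectively. The median, -0.26, lay at percentile 32.4. Nr0b2, which encodes the repressor SHP of Cyp7a1, was the only member of the FXR and FGF15 list with a value and was 1.85-fold lower. Of 18 transporters of bile acids, sterols and phospholipids 6 had a value, and 4 of these were higher. Slco1a4 was 1.86-fold higher, Slc51a 1.83-fold, Slc10a2 1.79-fold and Abcg8 1.61-fold, and the median lay at percentile 89.1. Abcc3 was 1.59-fold and Slco2b1 1.57-fold lower. A row shared by Slc51b, also on this list, and Rasl12 was not counted here and had a difference of -0.97. Abcc3, Slco2b1 and this row are named after their values were seen.

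Drug metabolism genes went in both directions. Of the 7 CAR and PXR targets with a value, among 28 listed, 3 were higher and 4 lower, with the median at percentile 41.3. The 3 higher genes, Cyp2b9, Cyp2b13 (at least 2.41-fold) and Cyp2a4, are all members of the female-biased list, and the 4 that are not were lower. Cyp2a4 and Cyp2c55 are named after their values were seen. Cyp2c55, among the lower genes, had 2 rows of opposite direction, at -2.10 and 0.68, and its direction depends on which row is used. Of 24 NRF2 target and glutathione genes 11 had a value, and 8 of these were lower, with a median of -0.69 (1.61-fold lower) at percentile 12.4. Gstm3, a glutathione transferase, was 2.51-fold lower, Ephx1, microsomal epoxide hydrolase, 1.84-fold and Gstm6 1.80-fold, while Hmox1, heme oxygenase, was 1.92-fold higher. Tiparp was the only AHR target with a value, at 1.95-fold higher. Of 30 genes of amino acid breakdown and the urea cycle 4 had a value. Hal was 1.96-fold lower, Uroc1 1.56-fold and Gldc 1.55-fold, and the urea cycle gene Ass1 was 1.85-fold higher. Their median lay at percentile 27.4.

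Of 32 markers of macrophages and dendritic cells 12 had a named value, and all 12 were higher in the PN pool, with a median of 0.77 (1.70-fold). The other 20 had no named value. Marco, at 5.15-fold, was followed by Clec7a, a receptor for fungal glucans, at 2.95-fold, Gpnmb at 2.13-fold and Cd5l at 2.09-fold. The count lay at percentile 99.99 of the random lists and the median at percentile 97.0. Of 23 lymphocyte and NK cell markers 6 had a value and were higher, with Ccl5 at 2.09-fold, Cd3e at 1.96-fold, Nkg7 at 1.58-fold and Gzma at 1.58-fold. Their count lay at percentile 98.7 and their median at percentile 75.6. The largest of these differences, 1.07 for Ccl5, lay under 1.11, the 95th percentile of the absolute difference of chemosensory receptor genes. Of these lymphocyte and NK cell markers, 2 had a higher value at or above 5.18, the median over named genes. Of 17 neutrophil markers 4 had a value. S100a9 was 2.18-fold higher, S100a8 2.04-fold and Csf3r 1.52-fold, and Lcn2, which hepatocytes also express, was 2.00-fold lower. Their median lay at percentile 94.1. None of 15 endothelial markers had a named value. Of 13 cholangiocyte markers 3 had a value. Epcam was 1.82-fold lower and Tspan8 1.51-fold lower, and Prom1, also a member of the female-biased list, at least 2.01-fold higher, with the median at percentile 36.9. Of 19 erythroid markers Car1 and Klf1 had a value and were 1.78-fold and 1.68-fold lower. Of 23 exocrine pancreas markers Ctrb1, Zg16 and Prss2 had a value and were 1.96-fold, 1.88-fold and 1.60-fold lower, with the median at percentile 1.24 and the count at percentile 3.85. Of 7 adipocyte markers Retn alone had a value and was 1.62-fold lower. Of 14 skeletal muscle and mesothelial markers, Upk3b was 1.58-fold higher and Msln 1.53-fold lower.

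Of 37 acute phase genes 10 had a value and were divided, with 5 higher and 5 lower and the median of -0.09 at percentile 34.4. With rows of several symbols counted, which adds the row shared by Saa1 and Saa2 at -1.73, the median lay at percentile 0.315. Orm3 and Orm2 were lower, as given above, and Saa3, a serum amyloid gene expressed largely outside hepatocytes, was 2.37-fold higher, as was Socs3, a feedback inhibitor of cytokine signalling, at 2.29-fold. Of the interferon response list 2 of 37 genes had a named value, Igtp at 1.98-fold higher and Ifit3 at 1.85-fold lower. Of 26 extracellular matrix and stellate cell genes 2 had a value. Lum was 1.91-fold higher and Tgfb1 1.76-fold higher. A row shared by Loxl2, also on this list, and a predicted gene was not counted here and had a difference of -1.09. That row is named after its value was seen.

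Among the remaining lists, the 3 ER stress and amino acid response genes with a value, of 27 listed, were higher, with Atf3 at 2.32-fold, Nupr1 at 2.23-fold and Dnajb9 at 1.55-fold. Their median lay at percentile 98.9 and their count at percentile 93.0. Of 23 circadian clock genes 6 had a value, and 4 of these were higher. Noct was followed by Per1 at 1.92-fold and Nampt at 1.59-fold, while Tef was 1.72-fold lower, and the median lay at percentile 76.0. Of 38 cell cycle genes 5 had a value, and 3 of these were lower. Cdkn1a, the cell cycle inhibitor p21, was 2.91-fold lower, Rrm2 1.71-fold and Bub1b 1.71-fold, and Ccnd1, cyclin D1, was 1.78-fold higher. The median lay at percentile 7.06. Of 15 iron metabolism genes 3 had a value. Tfrc, the transferrin receptor, was 2.08-fold higher, Hjv, hemojuvelin, 1.94-fold lower and Id3 1.52-fold lower, with the median at percentile 40.8. None of the 14 heat shock genes had a named value.

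**Figure D3:**
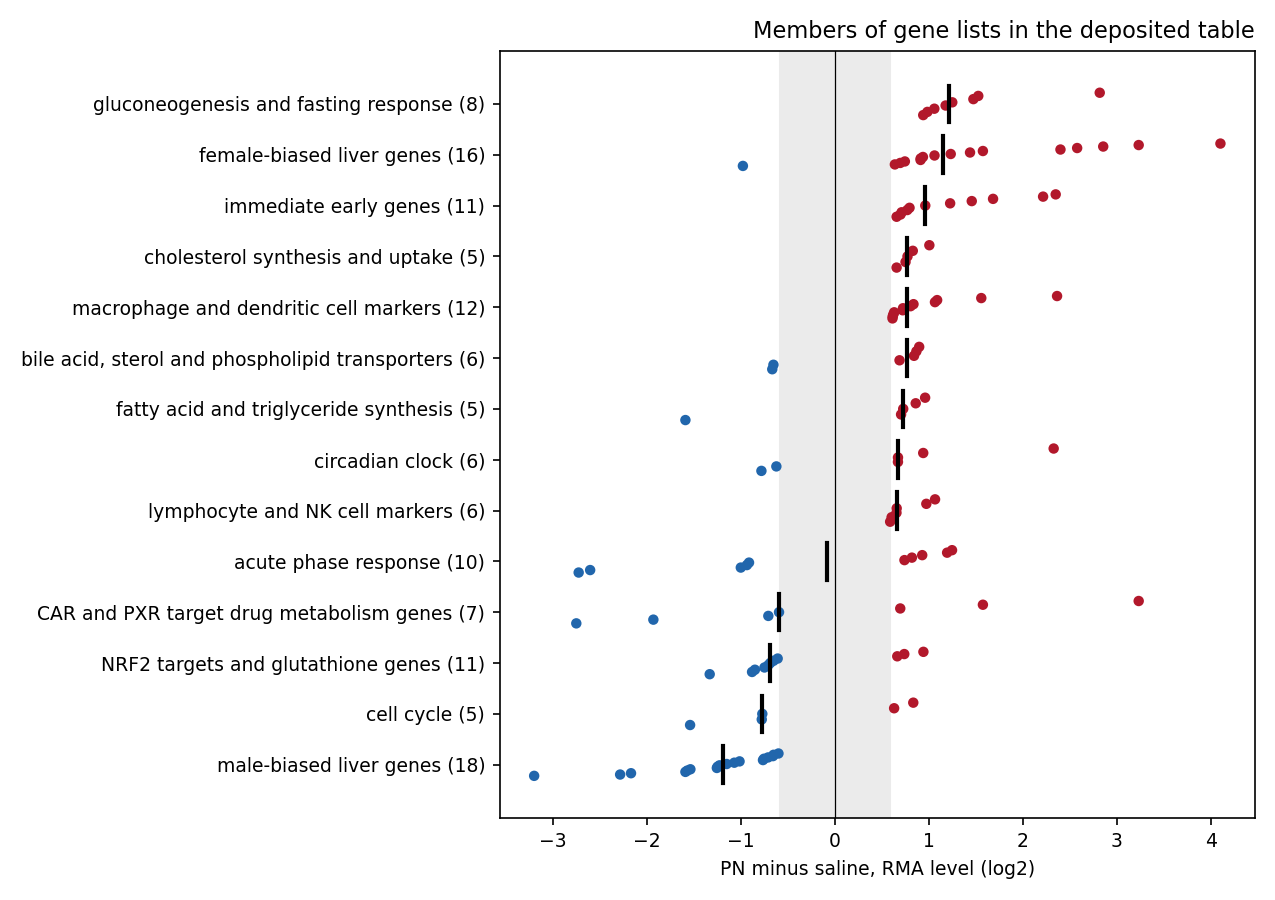
Difference between the PN and saline pools (x axis, log2) for each member of the gene lists with at least 5 members in the deposited table, number of members in parentheses. Red points are higher and blue points lower in the PN pool, black bars are medians, and the grey band is the range that the authors' 1.5-fold cutoff removed; the medians run from -1.19 for male-biased genes to 1.21 for gluconeogenesis and fasting response genes.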

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

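All tests in this part were chosen after the values were seen. They describe 1 array per group.

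The rows without a gene name entered no gene or list comparison. Probe set 17292632 had 2.59 in the saline pool and 6.80 in the PN pool, a difference of 4.20 on the log2 scale. Probe set 17205981 had 2.45 and 5.59, a difference of 3.14. Both saline values lie under the background level of 3.26, so the PN values were at least 11.6-fold and 5.03-fold higher. Both were picked out as signal above the control pool in rows the comparisons did not use. In the other direction, probe set 17201047 had a PN level of 3.00, also under the background level, and was at least 7.86-fold lower, while probe set 17207953 was at -3.13. Of the 3142 unnamed rows 1084 differed by at least 2-fold, against 289 of the 1940 named rows. The unnamed rows were also dimmer, with a median higher level of 4.59 against 5.21, and the cause of this contrast was not tested.

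The first pattern weighed is the opposite direction of sex-biased genes, with 33 of 34 members in their list's direction: male-biased lower, female-biased higher. A shift of the whole array would act on both lists alike, and their medians differed by 2.33. The pattern was picked for its opposite directions, and the cutoff removed small differences. The distance between the medians was thus fixed in advance and adds nothing to the pattern itself. The number of members in the list's direction lay at percentile 99.975 or above in both lists, among random lists matched on mean level. This cannot decide on independent noise of dim probe sets, since the pattern was picked among all lists for these directions. Close paralogs such as Cyp4a12a and Cyp4a12b can also share target sequence, so members need not be independent draws. Among bright genes all 17 male-biased members were lower and all 12 female-biased members higher. The directions were thus not confined to dim probe sets. Pools of unlike sex cannot be told apart from an effect of PN: of Xist and 4 Y-linked genes, 0 had a named row, which excludes nothing in a table of selected and partly unnamed rows. An effect of PN or of food removal on the hormonal control of these genes may therefore be considered only as an untested hypothesis.

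The second pattern is the higher level of fasting-response and immediate early genes. A uniform fasting state of the PN pool would lower lipid synthesis genes. Of the 10 cholesterol and fatty acid synthesis genes with a value 90% were higher, but the other 44 of the 54 listed had none, so this stays open. An unlike time of day at collection cannot be told apart from an effect of PN: only 2 of 5 clock output genes had a value. The larger of their absolute differences was 0.78. This set leaves out Noct, at 2.33, and Per1, at 0.94, which are members of the circadian clock list. Of the 6 members of that list with a value 4 were higher and 2 lower. The 0.78 is therefore no upper limit for clock genes. An effect of the infused nutrients, or of handling at collection, was not tested.

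The third pattern is the higher level of macrophage markers. The number of higher members lay at percentile 99.99 of random lists matched on mean level. This cannot decide on independent noise of dim probe sets, since the pattern was picked among all lists for its shared direction. All 12 markers were bright genes, so the direction was not confined to dim probe sets. The sizes were modest. The median of 0.77 lay near the median absolute difference of chemosensory receptor genes, 0.71. Of the 12 markers, 2 passed the 95th percentile of that absolute difference, 1.11. A lower share of hepatocytes in the PN pool would raise the markers of every other cell type alike, and cannot be told apart from more or activated macrophages. Outside the immune lists 4 of 13 markers with a value were higher (Clopper-Pearson 95% interval up to 61.4%, against an interval from 73.5% for macrophages). These intervals treat markers as independent draws, which genes of 1 cell type on the same arrays need not be, so they test no difference. The count of 4 lay at percentile 4 of random lists matched on mean level, inside their central 95%. Of the 9 lower markers 7 belong to blood or to cells from outside the liver. Of the 5 cholangiocyte and matrix or stellate markers with a value 3 were higher, as were the lymphocyte markers and 3 of 4 neutrophil markers. The row shared by the matrix gene Loxl2 and a predicted gene, at -1.09, is not among these 5.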

How the results depend on the processing

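The receptor limit (the 95th percentile of the absolute difference of chemosensory receptor genes), the lists without sex-biased members the division by gene name and the levels raised to background were chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Centring each array on its median, a shift of -0.02, is too small to turn the direction of any row and so shows nothing about stability. The 2405 higher and 2677 lower rows (47.3% higher) became 639 and 734 at 2-fold, 129 and 161 at 3-fold (44.5% higher), 1265 and 1276 among bright rows (49.8%), and 878 and 872 when genes were counted (50.2%), which turns the direction. They were 454 and 558 above the receptor limit (44.9%), 940 and 1000 in rows with a gene name, and 1465 and 1677 in rows without one. The smaller counts follow from fewer rows; the cause of the shifts in share was not tested. Of the 14 lists with at least 5 members, the share of higher members was 100% for female-biased genes among bright genes, at 2-fold and above the receptor limit, since Sult2a5 dropped out. At 2-fold and above the receptor limit, 1 gene was left for fatty acid synthesis (Elovl3, 0% higher, which reverses the share), NRF2 targets (Gstm3, 0%), cell cycle (Cdkn1a, 0%) and the clock (Noct, 100%). Without members of the sex-biased lists the share was 100% for fatty acid synthesis and 0% for CAR and PXR targets, and with the brightest row per gene it was 57.1% for the latter, a reversal due to Cyp2c55. List shares stayed within their intervals in 70 of 83 alternatives, and 3 moved to the other side of 50%, 1 of them inside its interval. Of the 85 alternatives for median percentiles 78 kept their side of 2.5 and 97.5. Both tallies include the centring, which could turn no row. The intervals of short lists are wide, such as 22.3% to 95.7% for the transporters, so a share could hardly leave them. Neither tally is therefore a measure of stability. The fasting-response median lay at percentile 91.7 at 2-fold and at 86.0 above the receptor limit, and the immediate early median at 97.4 above it. The macrophage median passed 97.5 with rows of several symbols (97.9) or unmatched random lists (99.0), and lay at 96.2 among bright genes and 95.1 at 2-fold. The acute phase median lay at 0.315 with rows of several symbols, and the CAR and PXR median at 0.10 without sex-biased members. The cause of these shifts was not tested. Of the 103 named genes 3 had a level under background; with it raised, the difference was 3.75 for Sult1e1, 1.27 for Cyp2b13 and 1.01 for Prom1. Signal over background limits the dim rows: 133 chemosensory receptor genes, which liver is not known to use, passed the authors' cutoff with a median higher level of 3.26, and their absolute differences reached a 95th percentile of 1.11 and a maximum of 1.41.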

Other observations

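Gene families in this part were singled out after their values were seen, and rows with several gene symbols are included.

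Of 7 Ccl chemokine genes other than the lymphoid ones, 5 were higher in the PN pool, with Ccl3 at 2.55-fold, Ccl6 at 2.48-fold, Ccl5 at 2.09-fold, Ccl7 at 1.73-fold and Ccl2 at 1.53-fold. Ccl8 and Ccl11 were 1.69-fold and 1.58-fold lower. The chemokines of lymphoid tissue were lower in 4 of 4 distinct rows: Cxcl13 by 2.33-fold, and rows shared by copies of Ccl21 and by Ccl19 with predicted genes, at -0.60 to -0.77. Genes of the Nat8 acetyltransferase family were lower in 4 of 4 rows, from -0.76 for Nat8f1 to -2.28 for the row shared by Nat8f3, Nat8f5 and Nat8f6. The carboxylesterase genes Ces3b, Ces2g, Ces1e and Ces2a were lower by 1.90-fold, 1.86-fold, 1.56-fold and 1.51-fold. Cyp2f2 was lower in both of its rows, at -1.25 and -1.35.

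Of the 9 rows of canonical histone genes with a level above background 7 were lower. The row of H2bc4, H2bc6 and H2bc8, whose PN level of 3.18 lies under background, was at least 5.95-fold lower, and H1f5 was 3.35-fold lower. H2bc12, whose saline level of 3.05 lies under background, was at least 1.45-fold higher. The 2 rows of H4f16 alone had opposite directions, at 0.60 and -0.64. Both distinct rows of the U3 small nucleolar RNA genes were lower, Rnu3a by 2.36-fold and the row shared by 4 Rnu3b copies by 1.74-fold. All 4 distinct rows of pancreatic amylase genes were lower, from -0.71 to -0.88, in the same direction as the exocrine pancreas markers Ctrb1, Zg16 and Prss2.

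With the rows sorted by mean level into 10 bins, the 3 dimmest bins had 34.6%, 42.7% and 44.9% of their rows higher in the PN pool. The other 7 bins lay between 47.6% and 53.1%, with no trend, and the brightest was at 48.0%. Of the 133 chemosensory receptor genes 42 were higher and 91 lower.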
